A study of Mus musculus with 18 samples.

How the data were processed

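RNA was measured in nuclear and cytoplasmic fractions of BV2 cells, an immortalised mouse microglial line, left untreated (0 h) or exposed to 10 µM oxyhemoglobin for 12 or 24 h. Each of the 6 combinations of fraction and time had 3 libraries, 18 in all. Per the labels' protocols, cells were detached with trypsin and lysed in a hypotonic buffer with NP-40. The nuclei were then pelleted by centrifugation and washed, and cytoplasmic RNA was precipitated from the supernatant. Libraries were made with a tagmentation kit, per the labels' protocols. Reads were aligned with HISAT2 2.2.0 to GRCm38 and counted with featureCounts, and DESeq2 was used for differential expression, per the submitters' processing notes. The strand setting and the annotation release are not given in the sources used here.

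The deposited count table has 6 columns, 1 per group. Every value multiplied by 3 was whole within 0.001, and 28.1% to 34.9% of the values per column were not whole themselves, so each column was read as the mean of the 3 libraries' counts. The deposited TPM values follow from these means and 1 length per gene. That length equalled the summed lengths of all annotated transcripts of a gene, within 0.1%, for 8612 of 8805 genes compared (97.8%), and the exonic bases counted once for 10 of them (0.114%). Gene symbols, classes and positions were taken from GENCODE M21 on GRCm38. Of the 55487 gene identifiers, 55227 were in that annotation and 346 had no symbol. No per-library values were analysed here, so no SD, p-value or test across libraries is given, and no result was checked against differences between replicates. The planned tests for replicated counts were replaced by the comparison of sizes described next. This replacement was chosen after a first look at the data. The number of deposited per-sample columns not used was 0.

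All computation was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Total counts were scaled by the trimmed mean of M-values (TMM), with 30% of the log ratios and 5% of the mean expression values trimmed at each end. The 3 nuclear and the 3 cytoplasmic means were scaled separately for the time comparisons. All 6 means were scaled together for nuclear against cytoplasmic ratios, so normalised counts per 1000000 (CPM) differ between these sets. The limits on CPM for comparing and naming genes, and the floor below, were taken on CPM per total counts, without the TMM factor. A gene was compared where the CPM of at least 1 group of the set reached the equivalent of 10 counts at the median depth. The log2 ratio of 2 groups was taken from the scaled means. Its 95% counting interval came from the summed reads of the 3 libraries (exact Clopper-Pearson interval of 1 group's share; a normal approximation for the change of a nuclear-to-cytoplasmic ratio). A gene was called higher or lower where the ratio was at least 2-fold and the interval excluded 0. These intervals cover counting error only, not differences between cultures. With a group at 0, the ratio was taken against a floor of 3 reads over the group and is given as a lower bound. The floor corresponds to 0.205, 0.189 and 0.187 CPM per total counts in the nuclear groups at 0, 12 and 24 h and to 0.134, 0.181 and 0.154 CPM in the cytoplasmic groups.

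A total of 31 gene lists were fixed before the data were examined, as were the comparisons and most of the other settings tried. The lists covered NF-kB inflammatory mediators, type I interferon response, NRF2 oxidative stress targets, heme and iron handling, ferroptosis and lipid peroxidation, alternative activation, homeostatic microglia, disease-associated microglia, lysosome and phagocytosis, cholesterol synthesis, liver X receptor and lipid efflux, ATF4 integrated stress response, ER chaperones, heat shock proteins, immediate early genes and p53 targets. They also covered DNA replication, mitosis, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, cytosolic housekeeping, replication-dependent histones, small nucleolar and spliceosomal RNAs, nuclear-retained noncoding RNAs, splicing factors, mRNA export and nuclear pore, other brain cells, erythroid cells, and fibroblasts and other leukocytes. Each list's median log2 ratio was set beside 10000 random lists of equal size matched on expression in 20 bins. Its percentile among them is a description and not a test.

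Genes were named by a rule fixed at the same time and changed in part afterwards. As used, it took the 8 highest and 8 lowest genes past the size threshold with a mean of at least 5 CPM and a plain symbol. It also took up to 4 members of each list with the largest absolute log2 ratios and a mean of at least 1 CPM, and 17 fixed genes. The planned rule took the list members with the lowest adjusted p, and ranking by size replaced this. Size ranking can favour genes with few reads. The conditions on adjusted p and on separate replicates were dropped, since neither could be computed. The planned rule did not cover 24 h against 12 h, to which it was extended. The text leaves out some list members and the lower part of the highest and lowest genes. Genes named outside the rule are said to be chosen after their values were seen.

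For every gene, the share of its exonic sequence that belongs to a single annotated transcript was computed. A base also covered by a transcript of another gene, on either strand, was not counted in this share. Genes with under 20% are called uncertain beside their value. Genes from 20% to 80% carry no mark, among them Nos2 with 24.6%. The nuclear-to-cytoplasmic ratio of protein-coding genes differed across that range too, so unmarked values may also be affected. Genes with at least 80% were also counted separately, for a reason given in the closing section.

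The procedure was tested on simulated data with known fold changes. For nuclear 12 h against 0 h (17093 genes, counting error only), 98.5% of 2.5-fold changes were called, 0.142% of unchanged genes were called, and the intervals covered 95.6% of true ratios. With added variation between libraries (17089 genes), these values were 80.6%, 0.841% and 61.0%. For cytoplasmic 12 h against 0 h, coverage was 95.7% with counting error alone (10758 genes) and 57.6% with added variation (10864 genes). For the change of the nuclear-to-cytoplasmic ratio at 12 h it was 91.1% (17661 genes) and 69.9% (17746 genes). False calls were most frequent there, with 1.25% of unchanged genes called with counting error alone and 3.93% (690 of 17546) with added variation, where 73.1% of 2.5-fold changes were called. In the cytoplasm 0.133% and 1.04% of unchanged genes were called. True coverage therefore depends on a spread between libraries that the group means do not show. Of 100 random simulated lists without a shift in nuclear 12 h against 0 h (17295 genes), 2% lay above and 8% below the central 95% of their random counterparts. With a shift of 0.5, 91% lay above it.

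Alternatives tried were median-of-ratios size factors, upper-quartile and total-count scaling, other filters, and log2 TPM with a pseudocount of 1 or 0.1. Further ones were other sets of groups scaled together, a prior of 2 reads per library, and genes with at least 80% single-transcript sequence. A last one left out every gene among the 20 with the most counts in any of the 6 groups.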

Results

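RNA sequencing covered nuclear and cytoplasmic fractions of BV2 cells, a mouse microglial line, before and after 12 or 24 h with 10 µM oxyhemoglobin, the oxygen-carrying blood pigment. The 6 groups held 3 libraries each, and every value below rests on the authors' mean over these 3 libraries, without a measure of spread between them. Summed over the 3 libraries, the nuclear groups at 0, 12 and 24 h held 14652566, 15899566 and 16031875 counts. The cytoplasmic groups held 22379595, 16537318 and 19537309. A mean count of at least 10 was reached by 16306, 15825 and 15836 genes in the nuclear groups and by 10780, 10126 and 11097 in the cytoplasmic groups. The unnamed gene ENSMUSG00000118642 took 18.6%, 16.3% and 22.1% of the nuclear counts. In the cytoplasm the highest gene was mt-Co1, the mitochondrial cytochrome c oxidase subunit 1, with 3.58%, 2.30% and 3.68%. Across 6158 genes, which are not independent replicates, the Pearson correlation of log2 levels was 0.93 between nuclear 0 and 12 h, 0.98 between nuclear 12 and 24 h, and 0.59 between the fractions at 0 h. Highest and lowest genes below are those with a mean of at least 5 CPM per total counts, a plain gene symbol and reads in every group compared. There was no untreated group at 12 or 24 h, so time in culture and treatment were not separated.

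The first comparison asked which nuclear RNAs differed after 12 h of oxyhemoglobin. Genes of inflammation stood at the top. Csf3 (chromosome 11, 98701263 to 98703629), the granulocyte colony-stimulating factor, was 177-fold higher, with 5.67 normalised CPM at 0 h and 1007 at 12 h (log2 ratio 7.47, 95% counting interval 7.18 to 7.78). Il1b, which encodes interleukin-1 beta, was 111-fold higher (0.915 to 102 CPM; log2 ratio 6.80, interval 6.07 to 7.64), and Il1a was 66.3-fold higher. The microRNA gene Mir6236 (log2 ratio 6.03, interval 4.46 to 8.32) and Ntng2 (5.83), a membrane-bound netrin, came next, followed by Tnfrsf8 (5.62, uncertain) and Il6 (5.48). The lowest were Olfr116 (log2 ratio −3.32, interval −3.61 to −3.04) and Olfr112 (−3.29, from 109 to 11.2 CPM), both annotated as olfactory receptors, followed by D7Ertd443e (−3.10) and their neighbour Olfr114 (−2.97, uncertain).

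Among the lists, NF-kB inflammatory mediators had 31 of 47 measured members higher and 1 lower in the nucleus, with a median log2 ratio of 1.89 above all 10000 random lists. Ptgs2, the inducible cyclooxygenase, was at 3.51 (86.6 to 986 CPM), the chemokine gene Ccl2 at 2.91 and Nos2, the inducible nitric oxide synthase, at 2.68. Type I interferon response genes had 14 of 41 higher and none lower (median 0.77), among them Cxcl10 (2.67), Ifit3 (2.56) and Isg15 (2.55). NRF2 oxidative stress targets had 11 of 31 higher and 1 lower (median 0.52), with Slc7a11, the cystine importer, at 2.71 (506 to 3313 CPM) and Srxn1, which repairs oxidised peroxiredoxins, at 2.25. Heme and iron handling had 8 of 29 higher and none lower (median 0.43). Hmox1 (chromosome 8, 75093621 to 75100589), which degrades heme, was at 2.26 (126 to 602 CPM, interval 2.19 to 2.33), and Slc48a1, a heme transporter, at 1.54. Within ferroptosis and lipid peroxidation 3 of 22 genes were higher and none lower.

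Protein folding and sterol genes formed a further group in the nucleus. ER chaperones had 12 of 27 higher and none lower (median 0.91), with Pdia4 at 1.76 (119 to 403 CPM) and Creld2 at 1.73. Of the heat shock proteins 3 of 17 were higher and none lower (median 0.59), with Bag3 at 1.27. Cholesterol synthesis had 9 of 23 higher and 1 lower (median 0.77), with Hsd17b7 at 2.38 and Lss, lanosterol synthase, at 1.68. Only 4 of 32 ATF4 integrated stress response genes were higher and none lower, with Gdf15 at 2.99. Immediate early genes had 7 of 27 higher and 4 lower, and p53 targets 3 of 22 higher and 2 lower. Housekeeping genes of the cytosol had 3 of 20 higher and none lower, Actb (beta-actin) at 1.81 and Gapdh, a glycolytic enzyme, at 0.52, under 2-fold.

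Lists of microglial states had lower members beside higher ones. Of 28 disease-associated microglia genes 8 were lower and 2 higher in the nucleus (median −0.18, or 0.14 among members with at least 80% single-transcript sequence), with Atp6v0d2, a proton pump subunit, at −1.80 and Igf1 at −1.59 (78.2 to 26.0 CPM). Homeostatic microglia genes had 5 of 23 lower and 3 higher (median −0.48), including Mertk, a receptor for apoptotic cells, at −1.72 and Tmem119 at 2.06. Alternative activation genes went both ways, 5 of 17 higher and 4 lower. Their members included Socs3 at 2.73, Mrc1, the mannose receptor, at −1.76 and Arg1, arginase 1, at −1.03 (13.1 to 6.39 CPM). Lysosome and phagocytosis genes had 3 of 43 higher and 5 lower, with Msr1, a scavenger receptor, at 2.49 and Ctsz, cathepsin Z, at 1.44. DNA replication had 2 of 42 higher, mitosis 1 of 40 higher and 1 lower (median −0.24), and liver X receptor and lipid efflux 2 of 15 lower. Hypoxia and glycolysis had 2 of 32 lower, and nuclear-encoded oxidative phosphorylation 5 of 70 higher and 2 lower.

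Small nucleolar and spliceosomal RNAs had 27 of 63 higher and none lower in the nucleus (median 0.54), led by Rnu12, the U12 RNA of the minor spliceosome, at 4.40 (26.3 to 557 CPM), and by Scarna17 (4.17) and Snord13 (4.06). Splicing factors had 0 of 47 higher and 1 lower, with a median of −0.21 against 0.22 for random lists. Random lists matched on expression thus need not centre on 0. The distance of a list median from 0 is therefore not wholly the list's own, and most medians are given without that reference. Of the mRNA export and nuclear pore genes 1 of 46 was higher. Replication-dependent histones had 8 of 58 higher and none lower (median 0.59). Cytosolic ribosomal proteins had 3 of 83 higher and none lower (median −0.04), mitochondrially encoded genes 1 of 16 higher and 3 lower (median −0.24), and nuclear-retained noncoding RNAs 2 of 18 higher and none lower (median −0.02). Among the latter, Malat1 was at 0.13 and Neat1 at 0.74, both under 2-fold. Marker lists of other brain cells, fibroblasts and other leukocytes, and erythroid cells had only 4, 1 and 1 measured members in the nucleus, too few for a median. Their members included S100b at 0.78, Cd79a at −0.64 and Alas2 at 0.28 (uncertain). In total 1324 genes were higher and 1192 lower of 17295 compared in the nucleus at 12 h. Total-count scaling moved the median of all genes by −0.20 and TPM by −0.27, and then 31.9% and 31.4% of the called genes were higher instead of 52.6%, while the directions of the lists given here with a median of at least 0.4 did not turn.

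**Figure D1:**
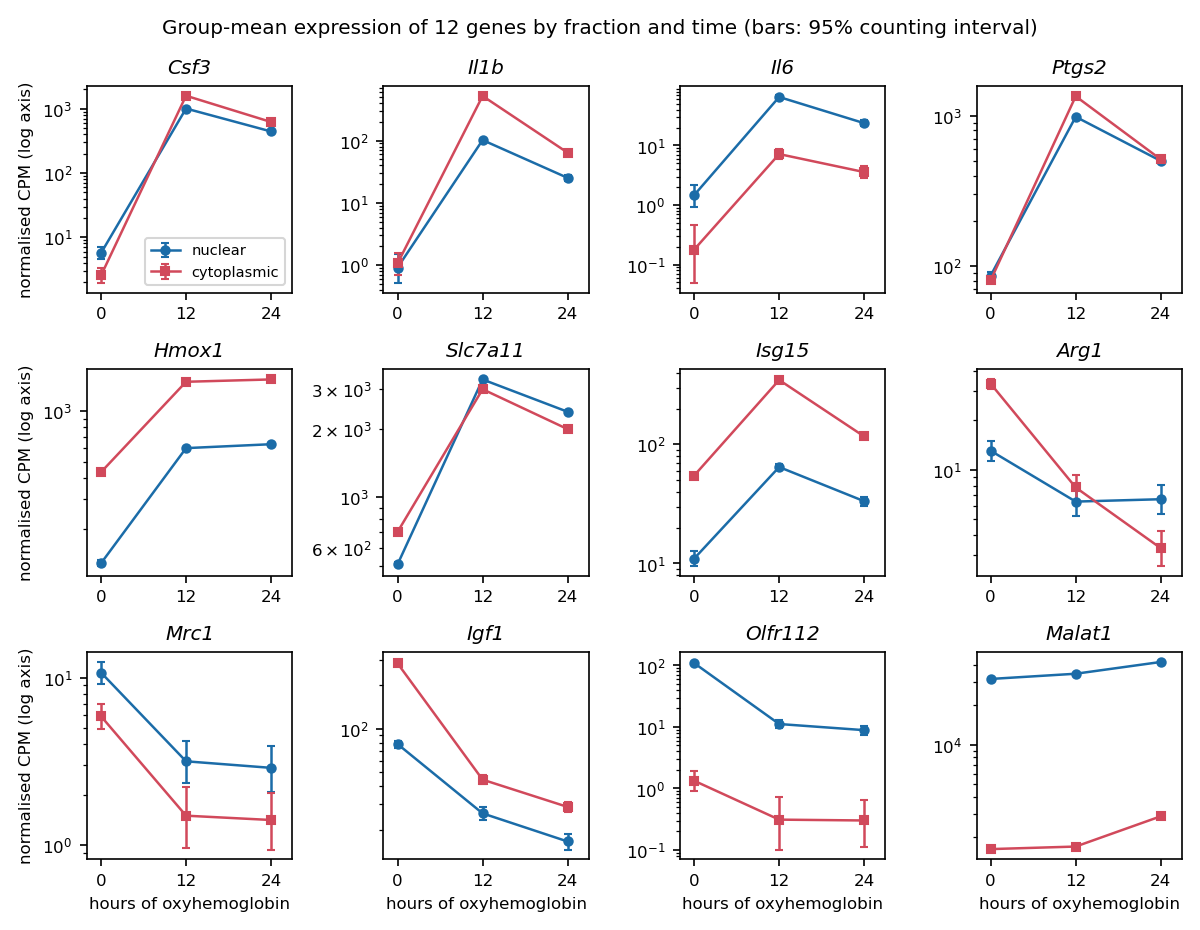
Normalised CPM (log axis) of 12 genes in the nuclear (circles) and cytoplasmic (squares) fractions against hours of oxyhemoglobin; points are the authors' means and bars are 95% counting intervals. Csf3 went from 5.67 to 1007 and 442 CPM in the nucleus at 0, 12 and 24 h, whereas Igf1 went from 282 to 44.4 and 28.8 CPM in the cytoplasm.

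At 24 h the nuclear fraction was compared with 0 h and with 12 h to ask which differences lasted. Csf3 was again highest (log2 ratio 6.29, interval 5.99 to 6.60, 442 CPM), followed by Ntng2 (5.49), the small nucleolar RNA Snord82 (5.29), the Y RNA Rny1 (5.29, interval 4.39 to 6.36), Snord66 (5.25) and Lta, encoding lymphotoxin alpha (5.19). The lowest genes were again Olfr112 (−3.62), Olfr114 (−3.54, uncertain), Olfr116 (−3.42) and Sema4g (−3.32), a semaphorin. NF-kB inflammatory mediators had 26 of 47 higher and 2 lower (median 1.28), with Il1b at 4.78, Il6 at 4.02 and Nos2 at 3.39. Hmox1 was at 2.34 (635 CPM), and 6 of 29 heme and iron handling genes were higher and none lower, with a median of 0.18 that was −0.13 under total-count scaling. NRF2 oxidative stress targets had 8 of 31 higher and 1 lower, with Slc7a11 at 2.24 and a median of 0.42, which was −0.12 on log2(TPM + 1). For type I interferon response the median was −0.00, with 4 of 41 genes higher and 2 lower, Isg15 at 1.60 and Mx1 at −1.75. Cholesterol synthesis had a median of 0.70 (7 of 23 higher), with Hsd17b7 at 2.37 and Stard4 at 1.79. ER chaperones had 5 of 27 higher, Pdia4 at 1.56, with a median of 0.25 that was −0.06 under total-count scaling. Small nucleolar and spliceosomal RNAs had 32 of 63 higher and 3 lower (median 1.03), with Rnu12 at 5.12 (915 CPM). Igf1 was at −2.24, Mrc1 at −1.89, Mef2c, a microglial transcription factor, at −1.29 and Tmem119 at 2.53. Histones had 7 of 58 higher and none lower (median 0.64), and Plk1, a mitotic kinase, was at 1.45 and Ccne1, cyclin E1, at 1.54.

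Between 12 and 24 h part of the inflammatory genes were lower in the nucleus. Il1b had a log2 ratio of −2.02 (102 to 25.2 CPM, interval −2.18 to −1.85), and Mmp13 (−2.49, 125 to 22.2 CPM) and Mmp12 (−2.16) encode matrix metalloproteinases. Gbp2, an interferon-induced GTPase, was lowest at −2.50. NF-kB inflammatory mediators had 6 of 47 members lower and none higher (median −0.44, under 2-fold), with Il6 and Il1a both at −1.46, and type I interferon response 14 of 41 lower and none higher (median −0.81). Higher at 24 h were Asprv1, a protease, at 2.32 (interval 1.74 to 2.95), the mitochondrial transfer RNA mt-Th at 2.29 and Mmp9 at 1.43. Hmox1 was at 0.08 and Nos2 at 0.71 between these times, both under 2-fold. In all, 1372 genes were higher and 991 lower at 24 h against 0 h, and 338 higher and 193 lower at 24 h against 12 h. Total-count scaling moved the median of all genes by −0.30 for 24 h against 0 h and TPM by −0.57, with 27.5% and 16.0% of the called genes higher instead of 58.1%. For 24 h against 12 h the shifts were −0.10 and −0.30, with 44.2% and 30.5% higher instead of 63.7%.

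In the cytoplasm, the question was which RNAs differed in the compartment where mRNA is translated. After 12 h, Csf3 was 627-fold higher (2.54 to 1593 CPM; log2 ratio 9.29, interval 8.92 to 9.69), Il1b 487-fold (1.07 to 521 CPM; 8.93, interval 8.35 to 9.57) and Il1a 154-fold (11.7 to 1794 CPM). They were followed by Tnf (5.98, uncertain), Rpph1 (5.78), the RNA of ribonuclease P, Il1f9 (5.73), a cytokine of the interleukin-1 family, and the chemokine gene Ccl7 (5.27, 123 to 4750 CPM). The lowest were Ipcef1 (−3.62, interval −4.17 to −3.11), Ctsf, cathepsin F (−3.40), Fam189a2 (−3.33) and Gpr183, an oxysterol receptor (−3.15, 87.7 to 9.85 CPM). Rpl30, a ribosomal protein gene, was at −3.05 (338 to 40.8 CPM).

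NF-kB inflammatory mediators had 28 of 44 cytoplasmic members higher and none lower (median 2.18), with Ptgs2 at 4.07 (80.7 to 1350 CPM), Nos2 at 2.83 and Il6 at 5.33 (interval 3.93 to 7.23). Type I interferon response had 14 of 38 higher and 2 lower, with Isg15 at 2.67 (54.7 to 347 CPM) and Gbp2 at 2.70, and a median of 0.76 that was −0.07 on log2(TPM + 1). Hmox1 was at 1.77 (434 to 1485 CPM, interval 1.74 to 1.81), while Steap3, an iron reductase, was at −2.89. Slc7a11 was at 2.09 (704 to 3001 CPM) and Nqo1, a quinone reductase, at 2.38. They belong to the NRF2 oxidative stress targets, of which 9 of 29 were higher and 1 lower, with a median of 0.57 (−0.12 on log2(TPM + 1)). Cholesterol synthesis had 7 of 16 higher and none lower, with Msmo1 at 2.28 and Hsd17b7 at 2.14, and a median of 0.96 that was −0.01 on log2(TPM + 1) of all genes with any TPM. Liver X receptor and lipid efflux had 4 of 13 lower and none higher (median −0.72), with Mylip, which encodes a ubiquitin ligase, at −1.71 and Soat1, which esterifies cholesterol, at −1.25 (764 to 322 CPM). Immediate early genes had 8 of 21 higher and 2 lower (median 0.52, −0.13 on log2(TPM + 1)), with Ier3 at 2.52 (325 to 1865 CPM).

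Homeostatic, disease-associated and lysosome lists had more lower than higher members in the cytoplasm, and most members under 2-fold. Homeostatic microglia genes had 8 of 19 lower and 1 higher (median −0.70), with Cd33 at −1.58 (687 to 229 CPM), and Trem2, a lipid-sensing receptor, was at −2.13 (23.4 to 5.36 CPM). Disease-associated microglia genes had 5 of 26 lower and 2 higher (median −0.37), Igf1 at −2.67 (282 to 44.4 CPM), Atp6v0d2 at −2.24 (416 to 88.3 CPM) and Cd68 at 3.51 (uncertain). Lysosome and phagocytosis had 8 of 39 lower and 2 higher (median −0.54), with Cd93 at −1.56 and, besides Cd68, Msr1 at 1.98. Alternative activation had 6 of 16 lower and 5 higher, with Arg1 at −2.10, Mrc1 at −1.97 and Ccl17, a chemokine, at 3.99. Mitosis had 4 of 38 lower and none higher (median −0.44), and DNA replication 3 of 35 lower (median −0.22), with the licensing factor Cdt1 at −1.59. Small nucleolar and spliceosomal RNAs had 15 of 27 higher and none lower (median 1.12). Eef1a1, a translation elongation factor, was at −1.23 (7553 to 3224 CPM), and cytosolic ribosomal proteins had 5 of 78 lower and 7 higher (median −0.32). Oxidative phosphorylation had 9 of 53 nuclear-encoded genes higher and 2 lower (median 0.26, −0.41 on log2(TPM + 1)).

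Some transcripts of other tissues had reads in the cytoplasm at 12 h, and carry-over into these libraries was not tested. Col1a1 and Col3a1, collagen genes of the fibroblast list, were at 0 at 0 h and both at least 18.7-fold higher at 12 h. Actc1, which encodes cardiac actin, had a mean count of 123 in the cytoplasm at 12 h and of at most 0.333 in any other group, and it was the lowest gene of the later comparison with 24 h (log2 ratio −8.84, interval −14.14 to −6.35). Of other brain cell markers, Cdh5, an endothelial cadherin, was at 2.57 and Mbp, a myelin protein, at −1.06. In total 1403 genes were higher and 1016 lower of 11751 compared in the cytoplasm at 12 h (58.0% higher). TPM moved the median of all genes by −0.72, with 21.4% of the called genes higher.

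**Figure D2:**
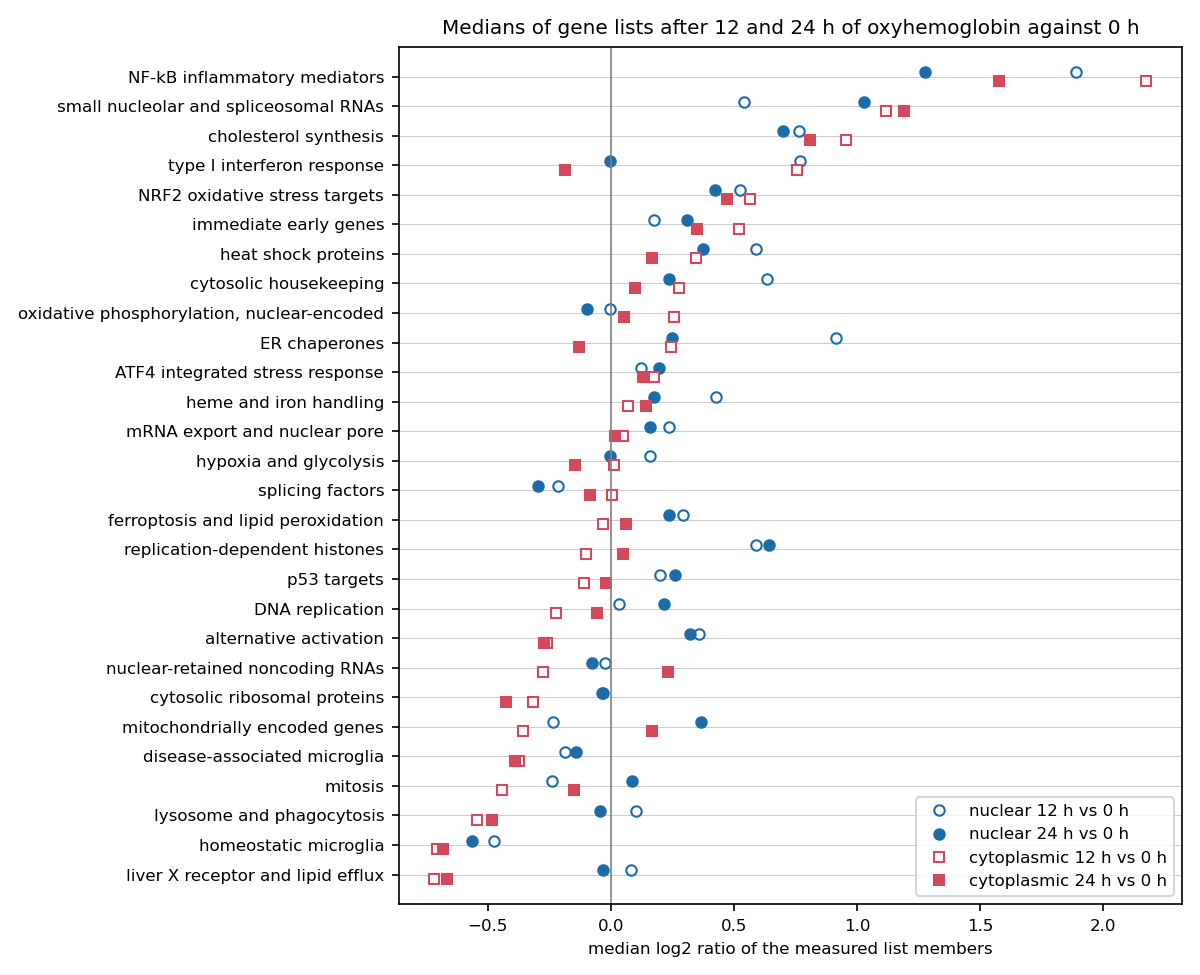
Median log2 ratio of the measured members of each gene list (horizontal axis) against 0 h, for nuclear (circles) and cytoplasmic (squares) RNA at 12 h (open) and 24 h (filled). NF-kB inflammatory mediators had the highest median of the lists drawn in each of the 4 comparisons, 1.89 and 1.28 in the nucleus and 2.18 and 1.58 in the cytoplasm.

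At 24 h in the cytoplasm Csf3 was at a log2 ratio of 7.93 (interval 7.56 to 8.34, 621 CPM) against 0 h. Rpph1 came next at 6.44 (8.38 to 727 CPM, interval 6.23 to 6.65), followed by Il1b (5.90) and Tnf (5.63, uncertain). The lowest were Srp54b (−3.52), a signal recognition particle protein, Arg1 (−3.33, 33.5 to 3.32 CPM, interval −3.72 to −2.97), Igf1 (−3.30, 28.8 CPM) and Selenbp1 (−3.00). NF-kB inflammatory mediators had 26 of 44 higher and 1 lower (median 1.58), with Nos2 at 3.06 and Ptgs2 at 2.67. Type I interferon response had 2 of 38 higher and 6 lower (median −0.19, or 0.11 among members with at least 80% single-transcript sequence), with Tap1, a peptide transporter of antigen presentation, at −2.14 and Psmb9, an immunoproteasome subunit, at −1.82. Hmox1 was at 1.82 (1533 CPM), Nqo1 at 3.55 and Slc7a11 at 1.51. Of ER chaperones with a mean of at least 1 CPM, only Edem1 (−1.76, uncertain) and Sdf2l1 (1.07) passed 2-fold. Of heat shock proteins by the same limit, only Hspa8 did, and it was lower (−1.14, 1604 to 730 CPM). Cholesterol synthesis had 5 of 16 higher and none lower (median 0.81), and liver X receptor and lipid efflux 3 of 13 lower and none higher (median −0.67), with Abca1, a cholesterol exporter, at −1.09 (482 to 227 CPM). Homeostatic microglia genes had 8 of 19 lower and 1 higher (median −0.68), and lysosome and phagocytosis 8 of 39 lower and 2 higher (median −0.48), with Cd68 at 3.73 (uncertain) the highest. Cytosolic ribosomal proteins had 16 of 78 lower and 5 higher (median −0.43), with Rpl3 at −1.62 (948 to 309 CPM). Malat1 was at 0.83 (1616 to 2863 CPM) and Xist at 0.04, both under 2-fold. In total 1331 genes were higher and 679 lower (66.2% higher), and TPM moved the median of all genes by −0.57, with 31.8% of the called genes higher.

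Between 12 and 24 h, cytoplasmic Il1b had a log2 ratio of −3.03 (521 to 64.0 CPM, interval −3.11 to −2.94), Il1a −2.04, Mmp13 −2.55, Gbp2 −2.20 and Ptgs2 −1.40. NF-kB inflammatory mediators had 12 lower and none higher (median −0.65), and type I interferon response 17 lower and none higher (median −0.91). Higher at 24 h were Rpl30 (2.28, 40.8 to 199 CPM), Pdzd2 (1.72), Mbp (1.63) and Airn (1.34), a long antisense RNA. Neat1, an architectural RNA of nuclear paraspeckles, was at 1.01 (223 to 449 CPM). In all, 387 genes were higher and 195 lower.

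**Figure D3:**
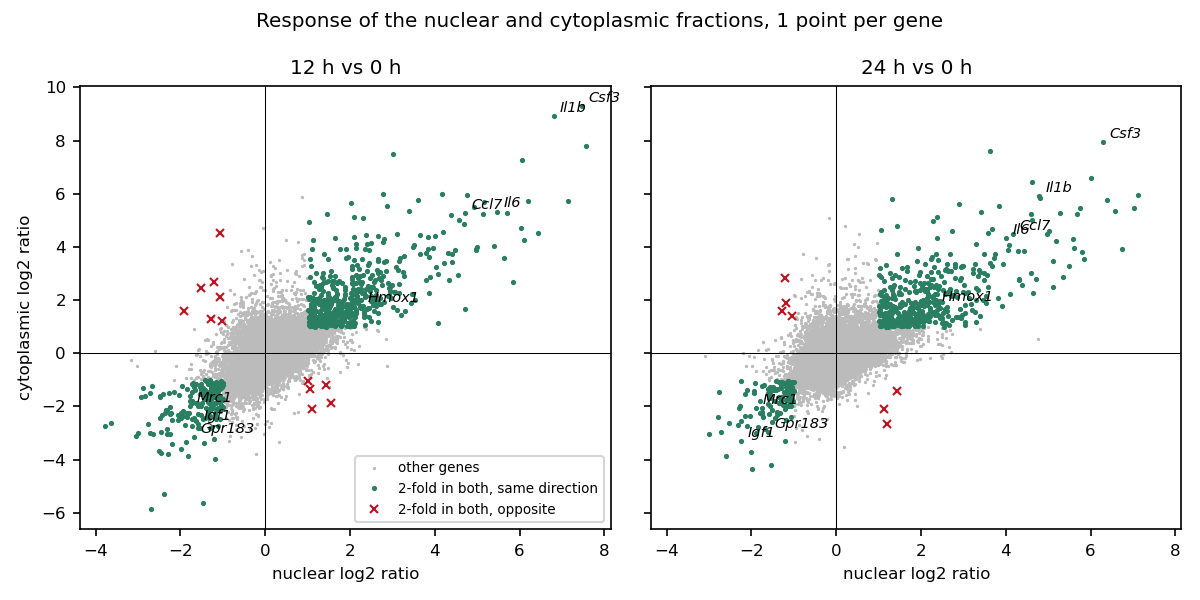
Cytoplasmic log2 ratio (vertical axis) against nuclear log2 ratio (horizontal axis) at 12 h (left) and 24 h (right) against 0 h, 1 point per gene. Of 11085 genes, 500 and 457 were higher in both fractions and 210 and 121 lower in both, whereas 12 and 7 went opposite ways.

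Whether both fractions changed alike was asked next, each against its own 0 h group. Per the labels' protocol both fractions come from the same lysate, and the labels do not say whether libraries of equal number share a culture, so the fractions are not treated as independent. Across 11085 genes, the Pearson correlation of nuclear and cytoplasmic log2 ratios was 0.63 at 12 h and 0.58 at 24 h, again across genes that are not independent replicates. At 12 h, 500 genes were higher and 210 lower in both fractions, and at 24 h these counts were 457 and 121. Unrelated calls in the fractions would give 108 and 29.7 at 12 h and 108 and 13.5 at 24 h. Carry-over of cytosol into the nuclear pellets, left open in the closing section, would also make the fractions move alike and was not separated from this. Higher in both fractions were Csf3, Il1b, Ptgs2, Hmox1 and Slc7a11, and lower in both were Igf1, Mrc1 and Atp6v0d2.

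The next comparison asked where each RNA lay in untreated cells. Long noncoding RNAs had a median log2 nuclear-to-cytoplasmic ratio of 2.29 (2390 genes, 1630 higher in the nucleus and 236 in the cytoplasm), small nucleolar and Cajal body RNAs 2.91 (273 genes), and protein-coding genes −0.34 (11213 genes). Other classes lay at a similar level, with 3.28 for microRNA genes, 3.12 for miscellaneous RNAs, 3.01 for small nuclear RNAs and 3.46 for genes annotated as unconfirmed. The value of 2.91 is therefore not particular to small nucleolar and Cajal body RNAs. Total-count scaling adds 1.36 to every ratio at 0 h, which turns the protein-coding median positive. Malat1 was at 3.07, Xist, the X-inactivation RNA, at 3.32, and Neat1 at 4.20. Nuclear-retained noncoding RNAs had 14 of 18 members higher in the nucleus and 2 in the cytoplasm (median 2.83), against a median of −1.83 for random lists. Splicing factor genes had 29 of 47 members higher in the nucleus (median 1.94, random −1.87), such as Srsf11 at 3.79. The random lists were matched on expression and not on the share of single-transcript sequence. The ratio of protein-coding genes differed with that share, as given below, so the gap for splicing factors cannot be read as location alone. The highest named genes rested on 1 cytoplasmic read over the group, with Zakit at 6.82 (interval 4.33 to 12.14), Ocrl at 6.79 (4.29 to 12.10), Capns2 at 6.49 (3.99 to 11.80) and Nxpe2 at 6.45 (3.95 to 11.76). Lowest were mt-Co2 (−6.36), mt-Co3 (−5.63), the Y RNA Rny3 (−5.60) and mt-Tn (−5.54). Mitochondrially encoded genes had 21 of 23 members higher in the cytoplasm (median −3.08), replication-dependent histones 54 of 60 (median −3.64) and cytosolic housekeeping genes 14 of 20 (median −2.22). Eef1a1 was at −4.42, Actb at −3.74 and Hmox1 at −2.99. NF-kB mediators had 27 of 49 members higher in the cytoplasm, with a median of −1.36 that was 0.01 under total-count scaling, and cytosolic ribosomal proteins 44 of 83, with a median of −1.24 that was 0.13. In total 8583 genes were higher in the nucleus and 5755 in the cytoplasm of 17902 compared (59.9%), or 78.9% with total-count scaling. Among genes with at least 80% single-transcript sequence the counts were 4321 and 2516.

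**Figure D4:**
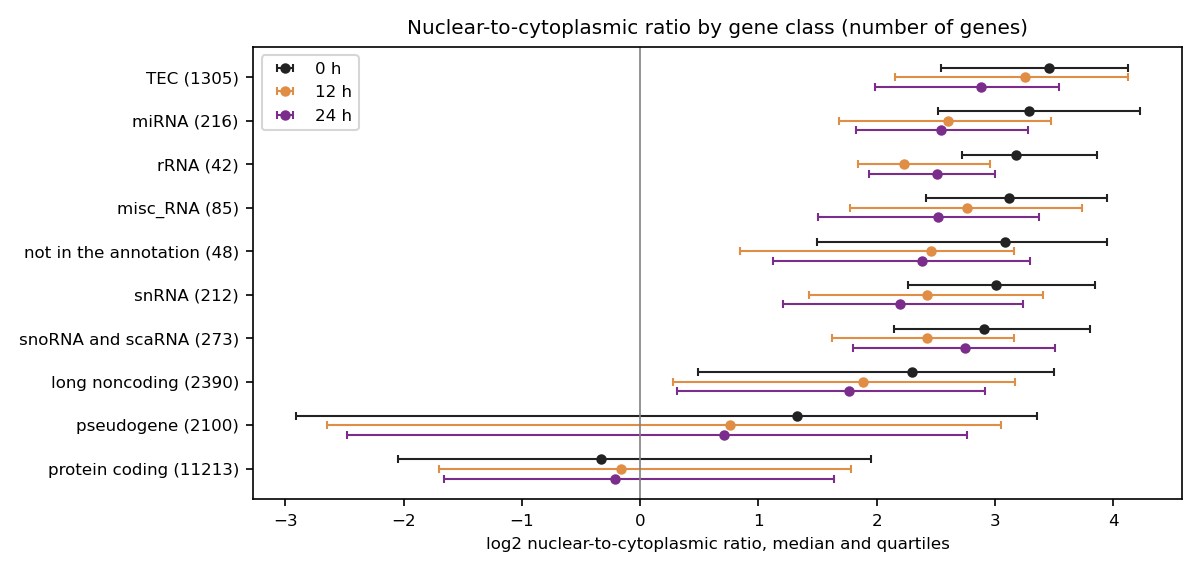
Median log2 nuclear-to-cytoplasmic ratio of gene classes (points) with quartiles (bars) at 0, 12 and 24 h. Long noncoding RNAs lay at 2.29, 1.88 and 1.77 and protein-coding genes at −0.34, −0.16 and −0.21; total-count scaling adds 1.36 at 0 h, 1.17 at 12 h and 1.03 at 24 h and turns the latter positive.

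The ratio differed with how much of a gene's exonic sequence belongs to a single annotated transcript. For protein-coding genes the median at 0 h was 1.2 where under 20% did (1307 genes), 0.83 for 20% to 40%, 0.12 for 40% to 60%, −1.15 for 60% to 80% and −1.97 for at least 80% (2286 genes). In that last class 412 genes were higher in the nucleus and 1530 in the cytoplasm. Long noncoding genes showed no such order, with medians of 1.67, 2.32, 1.79, 1.74 and 2.52.

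**Figure D5:**
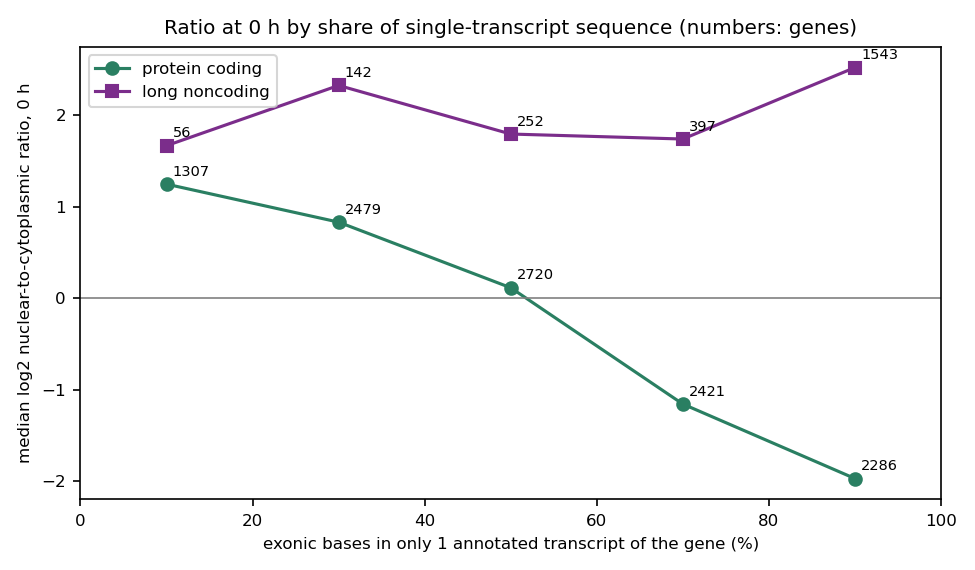
Median log2 nuclear-to-cytoplasmic ratio at 0 h (vertical axis) by the percentage of exonic bases in only 1 annotated transcript (horizontal axis), for protein-coding (circles) and long noncoding (squares) genes, with the number of genes at each point. Protein-coding medians run from 1.2 to −1.97; total-count scaling adds 1.36 to each.

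After oxyhemoglobin the nuclear-to-cytoplasmic ratios lay closer together. Their SD across genes was 2.63 at 0 h, 2.38 at 12 h and 2.22 at 24 h. At 12 h, 8117 genes were higher in the nucleus and 5398 in the cytoplasm, and at 24 h 8005 and 5367. With at least 80% single-transcript sequence the counts were 4240 and 2318 at 12 h and 4204 and 2280 at 24 h. Total-count scaling gave 80.3% and 78.9% higher in the nucleus at 12 and 24 h instead of 60.1% and 59.9%, and log2(TPM + 1) gave 78.9% and 70.4%. Long noncoding RNAs had medians of 1.88 and 1.77 at these times, small nuclear RNAs 2.43 and 2.2 after 3.01 at 0 h, and protein-coding genes with at least 80% single-transcript sequence −1.64 and −1.53 after −1.97. Total-count scaling adds 1.36, 1.17 and 1.03 to every ratio at 0, 12 and 24 h. It takes away most of this protein-coding rise and enlarges the fall of the noncoding classes, while the SD stays the same. Nuclear-retained noncoding RNAs made up 0.80%, 1.58% and 1.70% of cytoplasmic counts at 0, 12 and 24 h, and 7.12%, 7.37% and 7.60% of nuclear counts. Of this list Rn7sk, the small nuclear RNA of a transcription elongation regulator, took 0.50%, 1.28% and 1.19% of the cytoplasmic counts. Its share of the nuclear counts was lower at each time, with 0.17%, 0.40% and 0.53%, and rose as well. Without Rn7sk the list made up 0.29%, 0.30% and 0.52% of the cytoplasmic counts, of which Malat1 took 0.16%, 0.16% and 0.29%.

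Finally, the change of the ratio itself was compared to ask which RNAs moved differently in the fractions. At 12 h Rhoc, a small GTPase, had the largest shift toward the cytoplasm among genes with a mean of at least 5 CPM and a plain symbol (change of log2 ratio −3.88, interval −4.53 to −3.24), followed by Ocrl (−3.83, interval −6.77 to −0.89), Podxl (−3.59, interval −5.13 to −2.05) and Proser3 (−3.38). Srpk3, a splicing kinase gene, had the largest toward the nucleus (3.63, interval 1.56 to 5.71). Immediate early genes had 8 of 27 lower and none higher, among them Fos at −1.90 (interval −2.17 to −1.64), with a median of −0.45 against 0.32 for random lists, which was 0.17 on log2(TPM + 1). NF-kB mediators had 11 of 49 lower and 1 higher (median −0.15, random 0.34, and 0.22 on log2(TPM + 1)), such as Il1b at −2.09. Splicing factors had 4 lower and 1 higher (median −0.19, random 0.39, and 0.05 on log2(TPM + 1)). Histones had 15 of 60 higher and none lower (median 0.79, random 0.45), for example Hist1h2bf at 1.44. Neat1 was at 1.06, Arg1 at 1.11 and Malat1 at 0.11. At 24 h the highest were Snord13 (4.26), a small nucleolar RNA, Rn7s2 (2.65), an RNA of the signal recognition particle, Snord118 (2.43) and Arg1 (2.36, interval 1.86 to 2.86), and the lowest by the same limits Ocrl (−3.62, interval −6.55 to −0.70), Rhoc (−3.36), Capns2 (−3.27, interval −6.20 to −0.33) and F2rl2 (−3.24). Csf3 was at −1.64, Il1b at −1.11 and Hmox1 at 0.53. Mitochondrially encoded genes had a median of −0.02, against 0.38 for random lists. In total 1238 genes shifted toward the nucleus and 1351 toward the cytoplasm at 12 h, and 1037 and 1654 at 24 h (38.5% toward the nucleus). The balance depended on scaling and gene set. At 12 h it was 47.8% toward the nucleus, 31.2% with upper-quartile and 28.0% with total-count scaling, 66.8% on log2(TPM + 1), and 76.1% among genes with at least 80% single-transcript sequence (1161 and 364 genes). At 24 h it was 51.5% with median-of-ratios factors, 24.6% with upper-quartile and 10.1% with total-count scaling, 25.7% on log2(TPM + 1), and 64.5% among those genes (966 and 531). Upper-quartile and total-count scaling moved the median of all genes by −0.16 and −0.19 at 12 h and by −0.13 and −0.33 at 24 h. From 12 to 24 h, 420 genes shifted toward the nucleus and 808 toward the cytoplasm, or 193 and 473 with at least 80% single-transcript sequence. Toward the nucleus went 34.2%, against 20.7% with total-count scaling and 18.3% on log2(TPM + 1).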

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

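The minimum of 10 counts behind this selection was chosen after the values were seen. A total of 6 genes were singled out because the nuclear and the cytoplasmic fraction moved in opposite directions against 0 h, each by at least 2-fold, with a mean count of at least 10 over both times in each fraction. They were 3 of 12 such genes at 12 h and 3 of 7 at 24 h when no minimum was set. Since the deposited values are group means, the difference between fractions was not tested across libraries, and the intervals cover counting error only.

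At 12 h, Rpl21-ps15, a ribosomal protein pseudogene, had a nuclear log2 ratio of 1.09 and a cytoplasmic one of −2.08, and its nuclear-to-cytoplasmic log2 ratio differed by 3.21 (interval 2.93 to 3.49). Its mean count went from 60.3 to 122 in the nucleus and from 1385 to 234 in the cytoplasm. The predicted gene Gm7008 had 1.01 in the nucleus and −1.03 in the cytoplasm, a difference of 2.07 (interval 1.21 to 2.94). Cntd1, uncertain for its 15.4% of single-transcript sequence, had 1.05 and −1.36, a difference of 2.45.

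At 24 h, Nanp, a phosphatase of sialic acid synthesis, had −1.20 in the nucleus and 2.84 in the cytoplasm, a difference of −4.04 (interval −4.97 to −3.11). Its mean cytoplasmic count was 5.67 at 0 h, 3.67 at 12 h and 36 at 24 h. Mkrn1, which encodes a ubiquitin ligase, had −1.29 and 1.59, a difference of −2.87, and Plekho2 had −1.03 and 1.39, a difference of −2.41. Both are uncertain, with 14.9% and 16.4% of single-transcript sequence.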

How the results depend on the processing

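Some settings were chosen after seeing the data, and the others were set out beforehand. Those chosen after were total-count scaling, keeping genes with at least 80% single-transcript sequence, a prior of 2 reads per library and a minimum of 50 counts. Leaving out the genes among the 20 with the most counts in any group was also chosen then. Over 14 alternatives and 12 comparisons, 89 of 144 counts of genes stayed within 1.5 times the reported count. None of the comparisons moved beyond it with median-of-ratios factors, upper-quartile or total-count scaling, or without the genes with the most counts in any group. Their splits into higher and lower genes did depend on scaling, as given in the report. Of 6153 log2 ratios of named genes, 10 turned and 1816 moved beyond their counting interval. List medians were followed relative to the median of the genes compared, a definition set after a first calculation and changed once more after a second. By it, 17 of 3960 turned and 580 moved beyond the counting error. Without that reference, 350 of 3960 list medians changed sign, counting those of at least 0.1, most of them on the TPM scale and with total-count scaling, which shift all genes. No paired analysis was possible because the deposited values are group means, and for the same reason the DESeq2 and limma tests foreseen, replicate terms, leaving out of single libraries and list tests with an estimated correlation were not run. Depth limits genes with few reads in either fraction. A mean count of 10 was reached by 15825 to 16306 genes in the nuclear groups and by 10126 to 11097 in the cytoplasmic groups, although the latter held more counts in total.

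Without a filter beyond 1 count, more genes were compared and the counts were 3603 for nuclear 24 h against 0 h, 1089 for nuclear 24 h against 12 h, 3987 for cytoplasmic 12 h, 3630 for cytoplasmic 24 h and 1436 for cytoplasmic 24 h against 12 h. With a minimum of 50 counts, fewer genes were compared. The counts in the nucleus were 1108, 1042 and 91 for 12 h, 24 h and 24 h against 12 h, and 1047, 770 and 106 in the cytoplasm. They were 9045, 8759 and 8509 for the fractions at 0, 12 and 24 h, and 1386, 1547 and 614 for the change of their ratio. Among genes with at least 80% single-transcript sequence, again fewer genes, the same order gave 1383, 1347 and 298, then 1086, 869 and 293, then 6837, 6558 and 6484, and 1525, 1497 and 666. A prior of 2 reads per library, which draws ratios of low counts toward 0, gave 311 for nuclear and 378 for cytoplasmic 24 h against 12 h, and 1768 and 564 for the change of the ratio at 24 h against 0 h and 12 h. Scaling all 6 groups together gave 1131 for cytoplasmic 24 h against 12 h.

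On log2(TPM + 1) with a mean TPM of at least 1 the counts were 3696 for nuclear 24 h, 880 for nuclear 24 h against 12 h, 3675 for cytoplasmic 12 h, and 4196 and 2095 for the change of the ratio at 12 h against 0 h and at 24 h against 12 h. On log2(TPM + 0.1) they were 5412, 1560 and 5125 for the first 3 of these, 3761 for cytoplasmic 24 h, 1490 for cytoplasmic 24 h against 12 h, and 6673, 4977 and 4489 for the changes of the ratio. With any TPM above 0 they were 4137, 1124, 4239, 3163 and 1208, and 5072, 4247 and 2630, in that order. TPM takes no counting interval, so 2-fold alone made these counts.

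Genes that turned were Nos2 (0.29) and Ptgs2 (0.26) in the fraction comparison at 0 h with total-count scaling, and Tnf (uncertain) at 12 h with total-count scaling (0.005). On log2(TPM + 1), log2(TPM + 0.1) and with any TPM, Tnf at 12 h was at 0.03, 0.032 and 0.03 (uncertain) and Nos2 at 0.016, 0.018 and 0.016. For the change of the ratio at 12 h, Snord82 was at −2.30 on log2(TPM + 0.1). Lists that turned were mostly alternative activation, with −0.86 in nuclear 12 h, −0.31 in nuclear 24 h, 0.17 in cytoplasmic 24 h and −0.12 in the ratio change at 12 h without a filter. On TPM with any value this list was at 0.44 and 0.33 in cytoplasmic 12 and 24 h and −0.066 in the ratio change at 12 h, and among genes with at least 80% single-transcript sequence at 0.49 and 0.26. Immediate early genes were at −0.14 among the latter in cytoplasmic 24 h. Nuclear-retained RNAs were at 0.05 in cytoplasmic 12 h and 0.019 in the ratio change from 12 to 24 h with any TPM. Other brain cells were at 1.07 at 0 h with only the groups compared, at −1.42 without a filter and −0.55 with any TPM at 24 h, and at 0.14 in the ratio change at 24 h with any TPM. Homeostatic microglia genes were at −0.10 in the ratio change at 12 h with a minimum of 50 counts. For all of these the cause was not tested.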

Other observations

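The tests of few reads alone, of short RNA in the cytoplasm, of unlysed cells, of leakage and of genomic DNA were chosen only after the result they address was seen, as were the genes named in the first paragraphs here.

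A run of neighbouring olfactory receptor genes on chromosome 17 (Olfr112 to Olfr116, 37561668 to 37627199, GRCm38) was lower in the nucleus after oxyhemoglobin. At 24 h the log2 ratios were −3.62 for Olfr112, −2.41 for Olfr113, −3.54 for Olfr114, −2.87 for Olfr115 and −3.42 for Olfr116, and Olfr111 beside them was at −2.26. Olfr111, Olfr114 and Olfr115 are uncertain for their low share of single-transcript sequence. At 0 h these RNAs were mostly nuclear, with log2 nuclear-to-cytoplasmic ratios of 5.15 for Olfr112, 5.42 for Olfr113 and 6.16 for Olfr116. Of 8 transcripts of RNA polymerase III looked at, a set without a fixed list, all were higher in the cytoplasm at both times and in the nucleus at 24 h. At 12 h in the nucleus Rn7s1 was not called (0.79, interval −0.08 to 1.69). In the cytoplasm at 24 h the log2 ratios were 6.44 for Rpph1, 5.45 for Bc1, 5.26 for Rny1, 4.59 for Rny3, 3.96 for the vault RNA Vaultrc5, 2.48 for Rn7s2, 2.24 for Rn7s1 and 1.22 for Rn7sk. In the nucleus they were 4.63 for Rpph1, 5.29 for Rny1, 5.02 for Rny3, 5.60 for Vaultrc5 (interval 4.02 to 7.90), 7.02 for Bc1 (interval 4.51 to 12.34), 5.12 for Rn7s2, 1.48 for Rn7s1 and 1.93 for Rn7sk.

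Some transcripts had reads almost only in a single group. With a mean count of at least 5 there and at most 1 in each other group, there were 43 such genes in the nucleus at 0 h, 8 in the cytoplasm at 12 h, 0 in the cytoplasm at 0 h and 1 in each remaining group. The 8 cytoplasmic genes at 12 h included the heart muscle genes Actc1 (mean count 123), Myl7 (6) and Ckmt2 (5.33) and the connective tissue and pericyte genes Col3a1 (13.3), Dpt (9.33) and Rgs5 (8.33). Whether these reads were carried over from other material into a library was not tested, so they are not read as a response of the cells. Nuclear 0 h examples were Oprm1 (7.67), Vsig4 (7.33) and Hsf3 (8.33). Gm26444 had a mean count of 1308 in the nucleus at 12 h and at most 2.33 elsewhere, and Gm12626 had 185 in the cytoplasm at 0 h and at most 1.33 elsewhere.

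Protein-coding genes with little single-transcript sequence had few cytoplasmic counts and high nuclear-to-cytoplasmic ratios. Few reads alone is argued against, since among genes with at least 100 counts the medians at 0 h were −0.08 (355 genes with at most 20% single-transcript sequence) and −2.33 (1690 genes with at least 80%), a difference of 2.25. A candidate explanation is that reads in exonic sequence shared by several annotated transcripts were left out of the deposited counts. These transcripts could be of the same gene or of overlapping genes on either strand, and these cases were not separated. Of 166 protein-coding genes with at least 2 transcripts and no base that belongs to a single transcript, 1.81% reached a mean count of 10 in any group, against 57.1% of the 17310 others. Counts of genes with much shared sequence may then come largely from parts such as retained introns, which was not tested, and no biological explanation was tested either.

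The list of small nucleolar and spliceosomal RNAs had higher counts after oxyhemoglobin in both fractions, with 27 of 63 members higher in the nucleus at 12 h, and 32 higher and 3 lower at 24 h. The wider class of annotated small nucleolar, small nuclear and miscellaneous RNAs of at most 600 nt did not share this in its nuclear medians per gene, with 562 such genes at −0.10 at 12 h and −0.15 at 24 h (bootstrap interval −0.22 to −0.09). In summed nuclear counts, however, all annotated small nucleolar and Cajal body RNAs went from 0.28% at 0 h to 0.54% at 24 h and small nuclear RNAs from 0.19% to 0.47%, while the list went from 0.10% to 0.29%. In the cytoplasm 105 genes of the wider class had medians of 1.4 at 12 h and 1.23 at 24 h (bootstrap interval 0.98 to 1.55). In the nucleus, 76 protein-coding genes other than histones with transcripts of at most 600 nt had a median log2 ratio of 0.053 at 24 h (bootstrap interval −0.17 to 0.34). This argues against better recovery of all short RNA alike. The 58 histone genes, left out of that test, had a nuclear median of 0.64, so better recovery of some short RNA stays open. In the cytoplasm better recovery cannot be told apart from a difference of these RNAs themselves. There 59 short protein-coding genes other than histones had a median of 0.61, while 58 histone genes had 0.05. The rule for the nuclear test was reworded after a first look, and a further explanation by effective depth was dropped then. An effect of oxyhemoglobin on these RNAs stays open as a hypothesis, and libraries made for short RNA from both fractions would test it.

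Nuclear-to-cytoplasmic ratios lay closer together after oxyhemoglobin than at 0 h. More unlysed whole cells in the nuclear pellets is argued against, within limits. By 24 h, 23 mitochondrially encoded genes gained less nuclear ratio than nuclear-encoded genes of similar ratio at 0 h, by a median of −0.71 (bootstrap interval −0.84 to −0.31). Bootstrap intervals in this section cover the spread between genes only, and genes are not independent replicates. From 0 to 24 h, mitochondrially encoded genes went from 5.45% to 6.76% of cytoplasmic counts and from 0.64% to 0.67% of nuclear counts. A change of these RNAs themselves was not separated by the test, and carry-over of cytosol without mitochondria stays open. Leakage of nuclear RNA into the cytoplasm cannot be told apart, since only 5 long noncoding genes had enough reads. Their change of log2 ratio had a median of −0.25 at 24 h (bootstrap interval −0.92 to −0.05) and of 0.33, toward the nucleus, at 12 h. More genomic DNA in the nuclear libraries at 0 h stays open too, since 1374 olfactory and vomeronasal receptor genes outside the cluster above had 1.72 times the nuclear counts per total counts at 0 h of that at 24 h (interval 1.58 to 1.88), or 1.24 times (1.05 to 1.45) without the 10 with the most counts. With TMM factors these ratios were 1.39 (1.28 to 1.52) and 1.00 (0.85 to 1.18), so the outcome depends on scaling and on few genes. A treatment effect on RNA export or retention was not tested, and spike-ins in each fraction could separate it from these explanations.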
